A study of Mus musculus with 24 samples.

How the data were processed

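Total RNA from halved kidneys of male C57BL/6N mice, an inbred strain, aged 10 weeks, was measured on 24 Clariom S mouse arrays, which carry 1 set of probes per transcript and are read in 1 colour. The arrays fell into 4 groups by their labels. Sham animals that received the mock oligonucleotide and sham animals that received anti-miR-22 gave 5 arrays each, and the corresponding rhabdomyolysis groups gave 7 arrays each. Nothing in the labels states outright that each array came from a different animal, so the p-values measure the spread between these samples. The deposited values are on a log2 scale, and RMA and Partek 6.4 are named in the submitters' processing notes without roles or order. RMA is a method that corrects background, normalizes arrays to each other and summarises probes, which makes arrays comparable and compresses differences among dim probes. Per the labels' protocols, biotin-labelled DNA made from amplified RNA was hybridised. Settings of the normalization and any array batch are not given in the sources used here.

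The value table held 22206 lines of probes and 24 columns, all matched to samples by their titles. 1 line with values on only 5 arrays was left out, and no control line was present among the 22205 probes tested. 19572 probes had exactly 1 gene symbol, 0 had several and 2633 had none in the tables used. The Entrez identifiers of all 19572 were matched to a current gene table, which changed 0 symbols. They named 19505 distinct genes, 55 of them by more than 1 probe, and for these the probe with the highest mean over all arrays was named. Array medians lay between 5.752 and 5.857 and single values between 2.124 and 19.924. No detection call or background level was used, so folds against a group mean below the array medians are not exact, and none is given for the 5 named genes with the dimmest such means (3.46 to 4.19, where the arrays' lower quartiles were 3.909 to 4.028). An array gives no read depth, and the number of arrays limits the precision.

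Linear models of the 4 group means were fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The 6 contrasts were glycerol against sham with mock, glycerol against sham with anti-miR-22, anti-miR-22 against mock in sham animals, the same in rhabdomyolysis animals, the difference between these last effects, and their mean. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probes. A probe was called at an adjusted p below 0.05. Differences are given as log2 values with the standard error of the fit, and a fold is 2 raised to the size of that difference. Folds hold on the deposited scale, and whether that scale is proportional to RNA amount was not checked.

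Marker and pathway lists numbered 32, of which 14 named cell types and 18 named responses. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals, with adjustment over the lists within a contrast. Listed genes were matched by symbol, and by an older name only where no current gene bears it; this condition was set after the data had been seen and left 2 listed genes unmatched, C3 and Eno1. Members past the threshold were counted both over all probes and adjusted over the list alone. A score per array (the mean of the members' log2 values, each centred on its mean over all arrays) was compared by exact two-sided permutation. fry, a rotation test that asks whether the members move one way on balance, was run beside camera. The contrasts, tests, lists, alternatives and rule for named genes were fixed before the data were examined. That rule took the 10 highest and 10 lowest called genes per contrast (5 and 5 for the difference and the mean), up to 4 called members of each list, 2 per direction, and a few injury genes in every contrast. The text names a subset of the genes this rule allows, and that subset was picked after the values were seen. A planned test of genes with miR-22 seed sites was not run, because 3′ untranslated regions were not used here. 1 list of glutamine tract genes and 1 of Mediator subunits were added after the data had been seen.

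The tests were checked on simulated data with 22205 probes, in which 100 genes were shifted by 0.5 and 100 by 1 on the log2 scale. Of the genes shifted by 1, 88% were recovered for glycerol with mock, 90% for glycerol with anti-miR-22, 78% for anti-miR-22 in sham animals, 89% for anti-miR-22 in rhabdomyolysis animals, 52% for the difference and 99% for the mean. Of the genes shifted by 0.5, 19%, 16%, 15%, 22%, 2% and 57% were recovered in the same order, and 0 had the wrong sign. Only these genes were shifted, so the Benjamini-Hochberg cut-off was stricter than in real comparisons that called far more probes. The recovery rates do not carry over to those comparisons. Each contrast was also refitted over 100 splits of its samples.

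The alternatives were moderation with a trend and robust settings, no moderation, array weights, a second quantile normalization, median centring, leaving out dim probes, keeping only probes with 1 symbol, a 2-fold minimum, the replicate number as a block, the compared groups alone, and leaving out each array in turn. For the lists, an estimated correlation and fry were used in place of the preset correlation. Fits without sham mock arrays 1 and 3, and without these and 2 further arrays, were added after the data had been seen. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the tables, and matplotlib 3.10.9 drew the plots.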

Results

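Kidney gene expression was measured in a design that crossed acute kidney injury with an oligonucleotide against the microRNA miR-22. Rhabdomyolysis, the breakdown of skeletal muscle that floods the kidney with heme proteins, was induced by injecting 50% glycerol into leg muscle. Sham animals went through the same protocol without glycerol. Anti-miR-22, an antisense oligonucleotide complementary to miR-22-3p, or a mock oligonucleotide with 4 changed bases was given under the skin at 20 mg/kg, 24 h before the glycerol step. Both are 15 bases long, and they differ by T3A, A5T, T8A and A12T, with the anti-miR-22 base first and positions counted from 1 at the 5′ end. Kidneys were taken 24 h after the glycerol step. All animals had water withheld for 23 h and received carprofen, an anti-inflammatory analgesic, at 5 mg/kg. The protocol describes a mild and a severe glycerol dose, and the sample labels do not say which was used. There were 5 sham mock, 5 sham anti-miR-22, 7 rhabdomyolysis mock and 7 rhabdomyolysis anti-miR-22 arrays.

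The arrays separated by injury and by oligonucleotide. The first principal component held 59.1% of the variance, with sham arrays between -75.08 and -66.3. Rhabdomyolysis mock arrays lay between 39.32 and 52.07 on it, and rhabdomyolysis anti-miR-22 arrays between 48.62 and 63.18. The second component held 10.3%, with mock arrays between 14.44 and 36.65 and anti-miR-22 arrays between -31.7 and -16.27. Correlations between pairs of arrays ran from 0.949 to 0.9928, and all 24 arrays correlated best with the mean of their own group.

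**Figure D1:**
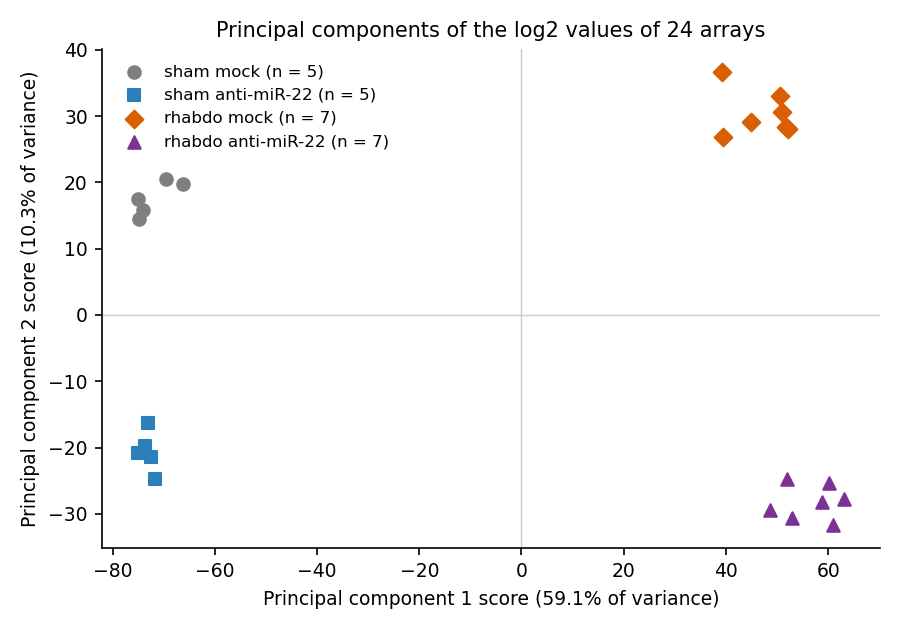
Each point is 1 of the 24 arrays, placed by its scores on the first principal component (59.1% of variance) and the second (10.3%). Sham and rhabdomyolysis arrays lie apart along the first axis, and mock and anti-miR-22 arrays lie apart along the second.

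The question of what glycerol injury changes was first asked in animals given the mock oligonucleotide. Genes of injured tubule rose steeply. Havcr1 (probe TC1100000483.mm.2), which encodes the kidney injury molecule shed by damaged proximal tubule, rose 974-fold (log2 9.93 ± 0.73, SE, n = 7 against 5, limma adjusted p = 1.59e-12). Lcn2, the gene of the siderophore-binding protein NGAL, rose 589-fold (9.20 ± 0.54, adjusted p = 1.15e-14). The 3 fibrinogen chain genes Fgg, Fgb and Fga, whose products are made mainly by liver, rose 629-fold, 395-fold and 299-fold. Egf, made in distal nephron segments, fell 501-fold (-8.97 ± 0.14, adjusted p = 1.98e-28). Of 22205 probes, 7641 (34.4%) were called, 4003 higher and 3638 lower.

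Of the 23 measured tubular injury markers, 22 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.59e-25; 0.000736 with an estimated correlation). The TWEAK receptor Tnfrsf12a rose 109-fold and the urokinase receptor Plaur 107-fold. Timp1, an inhibitor of matrix proteases (8.39 ± 0.33), and the epithelial keratin Krt20 (8.11 ± 0.42) rose from sham means of 3.53 and 4.19, below and just above the arrays' lower quartiles (3.909 to 4.028). No background level was used for such dim probes, so no fold is given. Igfbp7 was the member that fell (-0.36 ± 0.12, adjusted p = 0.0199); its adjusted p was 0.0507 to 0.0813 in 5 alternatives, among them the fits without sham mock 1 and without sham mock 2. Outside the list, Lrg1, a secreted glycoprotein of the acute-phase response, rose 162-fold. Sham mock 1 stood apart in these genes: its Havcr1 value was 14.59 where the other sham mock arrays lay between 7.00 and 7.74, and its Lcn2 value was 13.70 where they lay between 7.75 and 8.91. Without this array the log2 differences were larger, at 11.38 (2670-fold) for Havcr1, 10.27 (1230-fold) for Lcn2 and 8.72 for Krt20.

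Markers of nephron segments fell. All 12 thick limb and distal tubule genes fell, also when adjusted over the list alone (mean log2 -3.11, adjusted p = 3.44e-15; 0.000349 with an estimated correlation). They included Slc12a1, the sodium-potassium-chloride cotransporter of the thick limb, which fell 89.5-fold, and Umod, the gene of uromodulin, which fell 1.77-fold. Of 21 proximal tubule genes, 19 fell and 0 rose, and 20 fell when adjusted over the list alone (mean -1.94, adjusted p = 3.44e-15; 0.00551 with an estimated correlation). Gatm, which makes the creatine precursor guanidinoacetate, fell 57.7-fold, and the amino acid transporter gene Slc7a13 fell 27.4-fold. Of 13 collecting duct genes, 11 fell by either adjustment (adjusted p = 4.44e-07; 0.00534 with an estimated correlation), among them the water channel genes Aqp3 (-2.44 ± 0.26) and Aqp6 (-1.93 ± 0.20). In sham mock 3, Aqp3 was 11 where the other sham mock arrays lay between 10.01 and 10.24. Further steep falls were those of Fam107a (97.2-fold), G6pc, the glucose-6-phosphatase gene of gluconeogenesis (82.4-fold), Wfdc15b (75.2-fold), the organic anion transporter gene Slc22a22 (72.6-fold) and Abca13 (53-fold). Nccrp1 fell by 5.96 ± 0.19 on the log2 scale, to a dim mean of 3.80.

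**Figure D2:**
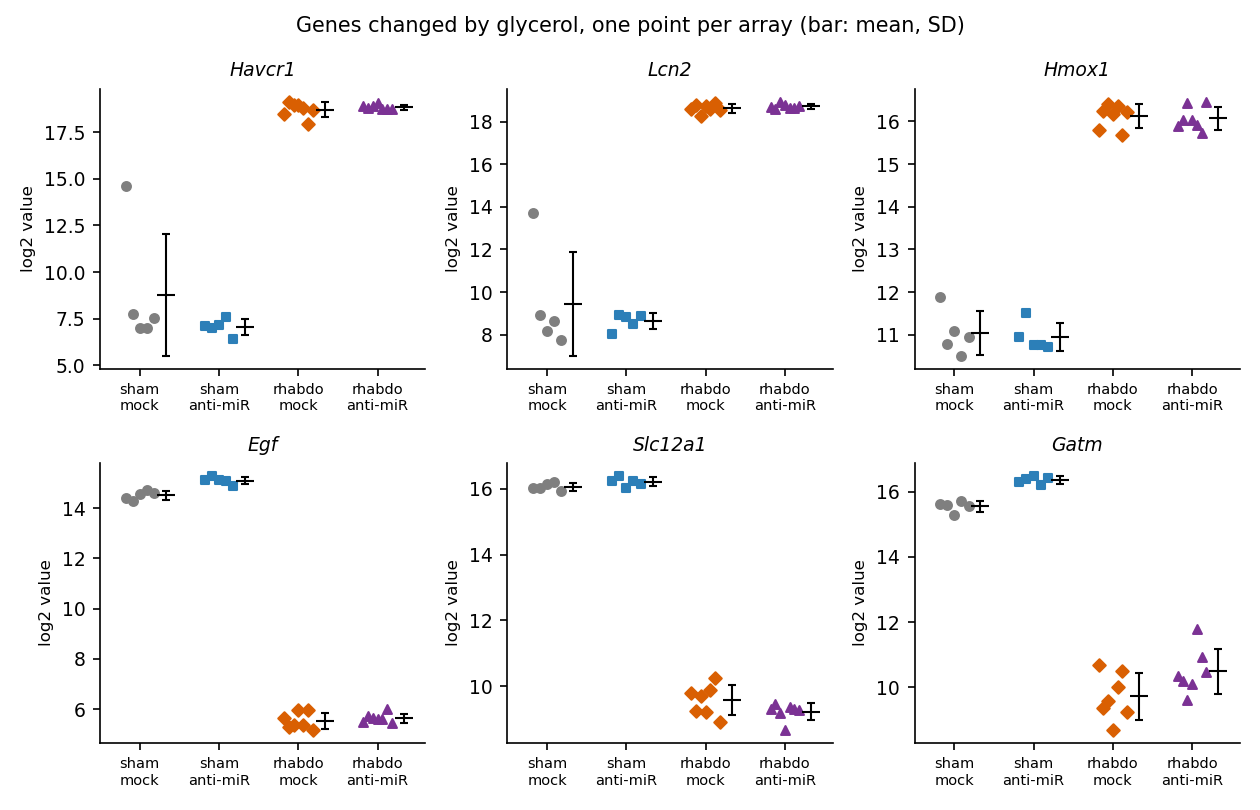
Log2 array values of Havcr1, Lcn2, Hmox1, Egf, Slc12a1 and Gatm in the 4 groups, with 1 point per array and the group mean with its SD. The first 3 genes are higher in rhabdomyolysis kidneys and the other 3 lower with either oligonucleotide, and sham mock 1 lies above its group for Havcr1 (14.59) and Lcn2 (13.70).

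Heme, oxidant and stress responses rose together. Of 17 heme and iron genes, 12 rose and 1 fell by either adjustment (adjusted p = 2.63e-06; 0.000349 with an estimated correlation). Hmox1, the heme oxygenase that degrades heme, rose 33.9-fold (5.08 ± 0.19), and Cp, the ferroxidase ceruloplasmin, rose 6.01-fold. The member that fell was Ireb2, an iron-responsive RNA-binding protein gene (-0.45 ± 0.18, adjusted p = 0.0475), and 19 alternatives, 16 of them the omission of 1 array, put its adjusted p between 0.0505 and 0.116. Of 18 NRF2 antioxidant genes, 15 rose and 1 fell by either adjustment (adjusted p = 2.03e-12; 0.00161 with an estimated correlation). The sulfiredoxin gene Srxn1 rose 18.5-fold and the metallothionein gene Mt2 22.3-fold, while the malic enzyme gene Me1 fell 1.60-fold. Of 16 immediate early genes, 14 rose, or 15 adjusted over the list alone (adjusted p = 4.01e-12; 0.000841 with an estimated correlation), among them Myc (57.8-fold) and Egr2 (14.7-fold). Of 26 inflammatory mediators, 20 rose and 0 fell by either adjustment (adjusted p = 1.12e-10; 0.000126 with an estimated correlation), including the cytokine genes Csf1 (19.6-fold) and Lif (17.8-fold). Of 18 matrix genes, 16 rose by either adjustment (adjusted p = 2.52e-13; 0.000349 with an estimated correlation), with tenascin C, encoded by Tnc, up 10.6-fold and the collagen gene Col3a1 7.44-fold. Stroma markers followed, with 7 of 10 higher and 1 lower by either adjustment (adjusted p = 0.00371; 0.041 with an estimated correlation).

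Some lists were called only at the preset correlation. The p53 target genes had 8 of 14 members higher by either adjustment (adjusted p = 0.000393; adjusted p = 0.0585 with an estimated correlation), among them Cdkn1a, the cell cycle inhibitor p21 (40.3-fold). Heat shock genes had 8 of 11 higher by either adjustment (adjusted p = 0.00127; adjusted p = 0.0527 with an estimated correlation), among them Hspb1 (12.5-fold). In the unfolded protein and integrated stress response 9 of 14 were higher and 1 lower by either adjustment (adjusted p = 0.00371; adjusted p = 0.0701 with an estimated correlation), with the asparagine synthetase gene Asns up 9.80-fold. Macrophage markers had 7 of 15 higher and 1 lower by either adjustment (adjusted p = 0.00549; adjusted p = 0.0954 with an estimated correlation), including the endotoxin co-receptor gene Cd14 (28.7-fold) and the integrin gene Itgam (5.97-fold). Cholesterol synthesis genes had 6 of 14 lower and 1 higher, or 2 higher adjusted over the list alone (adjusted p = 0.00678; adjusted p = 0.234 with an estimated correlation), with the lanosterol demethylase gene Cyp51 down 6.52-fold.

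Mitochondrial and clock genes also moved. All 19 respiratory chain genes fell by either adjustment (mean -0.85, adjusted p = 1.99e-10; 0.00534 with an estimated correlation), from the complex I gene Ndufs1 (-1.28 ± 0.13) to the ATP synthase gene Atp5b (-0.34 ± 0.10). Of 15 circadian clock genes, 10 fell and 3 rose by either adjustment (adjusted p = 0.000861; 0.00534 with an estimated correlation). The output factors Dbp and Hlf fell 13.4-fold and 10.2-fold, while Arntl and Npas2, activators of the loop, rose 4.66-fold and 3.93-fold. The lipid droplet gene Plin2 rose 65.5-fold, although the list of fatty acid oxidation genes was not called (4 higher and 8 lower by either adjustment, adjusted p = 0.255) and its mean of 0.01 differed in sign from its median of -0.22. Complement and fibrinogen, of which C3 was not analysed here, had 4 of 13 higher and 3 lower, or 4 lower adjusted over the list alone, and was not called (adjusted p = 0.153). Also not called were lists for interferon-stimulated genes (adjusted p = 0.401), cell cycle genes (0.355), hypoxia and glycolysis (0.401), earlier reported miR-22 targets (0.355), podocyte (0.401), endothelium (0.355), neutrophil (0.355), T and NK cell (0.355), B cell (0.632), red cell (0.355), skeletal muscle (0.938), adipose tissue (0.355) and adrenal gland (0.682). Among these uncalled lists, exact permutation tests of the scores passed for complement and fibrinogen, hypoxia and glycolysis and miR-22 targets (each adjusted p = 0.00213), red cell (0.0135), endothelium (0.022), neutrophil (0.0246) and T and NK cell (0.0488).

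The glycerol response with anti-miR-22 asked whether the same genes respond when this oligonucleotide is given in place of mock. Havcr1 rose 3520-fold (11.78 ± 0.73, n = 7 against 5, adjusted p = 2.6e-14), from a sham mean of 7.05 ± 0.42 (SD) that lay below the 8.78 ± 3.30 of sham mock, a group that holds the high array 1. Lcn2 rose 1080-fold, Fgg 1010-fold and Sox9, a transcription factor of regenerating tubule, 132-fold. Timp1 rose by 8.72 ± 0.33 on the log2 scale, again from a dim sham mean (3.46). Egf fell 698-fold, the cationic amino acid transporter family gene Slc7a12 155-fold, G6pc 154-fold, Slc12a1 127-fold and Mep1b, the brush border protease subunit meprin beta, 62.3-fold. Hmox1 rose 34.9-fold and Cdkn1a 37.0-fold. In all, 8303 probes (37.4%) were called, 4395 higher and 3908 lower.

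The glycerol responses with mock and with anti-miR-22, which share 0 arrays, correlated across probes at Pearson r = 0.925 and Spearman rho = 0.774, and probes are not independent replicates. Both comparisons called 6038 probes, of which 6026 had the same sign and 12 the opposite. 3216 were higher in both where independent lists would give 792.3, and 2810 were lower in both where they would give 640.3. Both comparisons use the same estimate of spread per probe, which by itself can raise the overlap above these values.

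With anti-miR-22, injury markers again had 22 of 23 members higher and 1 lower by either adjustment (adjusted p = 8.47e-24; 0.00167 with an estimated correlation). All 21 proximal tubule genes fell by either adjustment (mean -2.39, adjusted p = 1.64e-17; 0.00383 with an estimated correlation), with Gatm down 58.9-fold and Slc7a13 down 41.7-fold. All 12 thick limb genes (adjusted p = 2.89e-15; 0.00054 with an estimated correlation) and 12 of 13 collecting duct genes (1.75e-07; 0.00436 with an estimated correlation) fell by either adjustment. Respiratory chain genes had 17 of 19 lower, or 18 adjusted over the list alone (8.63e-09; 0.00998 with an estimated correlation). Clock genes had 10 of 15 lower and 3 higher by either adjustment (0.002; 0.00998 with an estimated correlation), with Dbp down 14.5-fold and Arntl up 4.16-fold.

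Rising groups were also shared. NRF2 genes had 17 of 18 higher and 1 lower by either adjustment (adjusted p = 1.27e-11; 0.00218 with an estimated correlation), heme and iron genes 11 of 17 higher, or 12 adjusted over the list alone, and 2 lower (0.000269; 0.00218), and inflammatory mediators 18 of 26 higher and 1 lower by either adjustment (4.47e-08; 0.00054). Immediate early genes had 13 of 16 higher, or 14 adjusted over the list alone (1.89e-11; 0.00168), including Klf6 (19.3-fold), and matrix genes 15 of 18 higher and 1 lower by either adjustment (1.14e-09; 0.002), including the matricellular growth factor gene Ccn2 (7.91-fold). The second value in each pair of parentheses is the adjusted p with an estimated correlation. The unfolded protein response (9 of 14 higher and 2 lower by either adjustment, 0.00134) and heat shock genes (8 of 11 higher by either adjustment, 0.000404) were called here with an estimated correlation as well (adjusted p = 0.0488 and 0.0337).

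Other lists were called with anti-miR-22 only at the preset correlation. These were p53 targets (8 of 14 higher, or 9 adjusted over the list alone, and 2 lower, adjusted p = 0.000847; adjusted p = 0.0778 with an estimated correlation) and cholesterol synthesis (8 of 14 lower and 2 higher, or 9 and 3 adjusted over the list alone, 0.00166; adjusted p = 0.154 with an estimated correlation). Fatty acid oxidation had 10 of 20 lower and 4 higher, or 11 and 4 adjusted over the list alone (mean -0.22, 0.0284; adjusted p = 0.387 with an estimated correlation), and was not called without sham anti-miR-22 array 3 (mean -0.12, adjusted p = 0.0565), the lowest of 3 alternatives that ended the call. The exact permutation p of its score was 0.135 (adjusted 0.154). Stroma markers, among them the smooth muscle gene Tagln (8.23-fold), had 6 of 10 higher and 1 lower, or 2 lower adjusted over the list alone (0.0435; adjusted p = 0.149 with an estimated correlation), and the call ended in 8 alternatives (0.051 to 0.149). Beside the estimated correlation these were a second quantile normalization (0.051), the replicate block (0.0531), leaving out dim probes (0.118), and the fits without sham anti-miR-22 array 4 (0.0557) or rhabdomyolysis anti-miR-22 array 2 (0.0542), 5 (0.066) or 6 (0.0536). Endothelium (0.0521), with the VEGF receptor gene Kdr down 3.87-fold, macrophage (0.0735) and neutrophil (0.201) were not called by camera (adjusted exact permutation p of the scores 0.00202, 0.00202 and 0.00842), although the neutrophil genes Retnlg (1.49 ± 0.25) and S100a8 (1.56 ± 0.28) rose from dim sham means of 3.99 and 3.69.

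**Figure D3:**
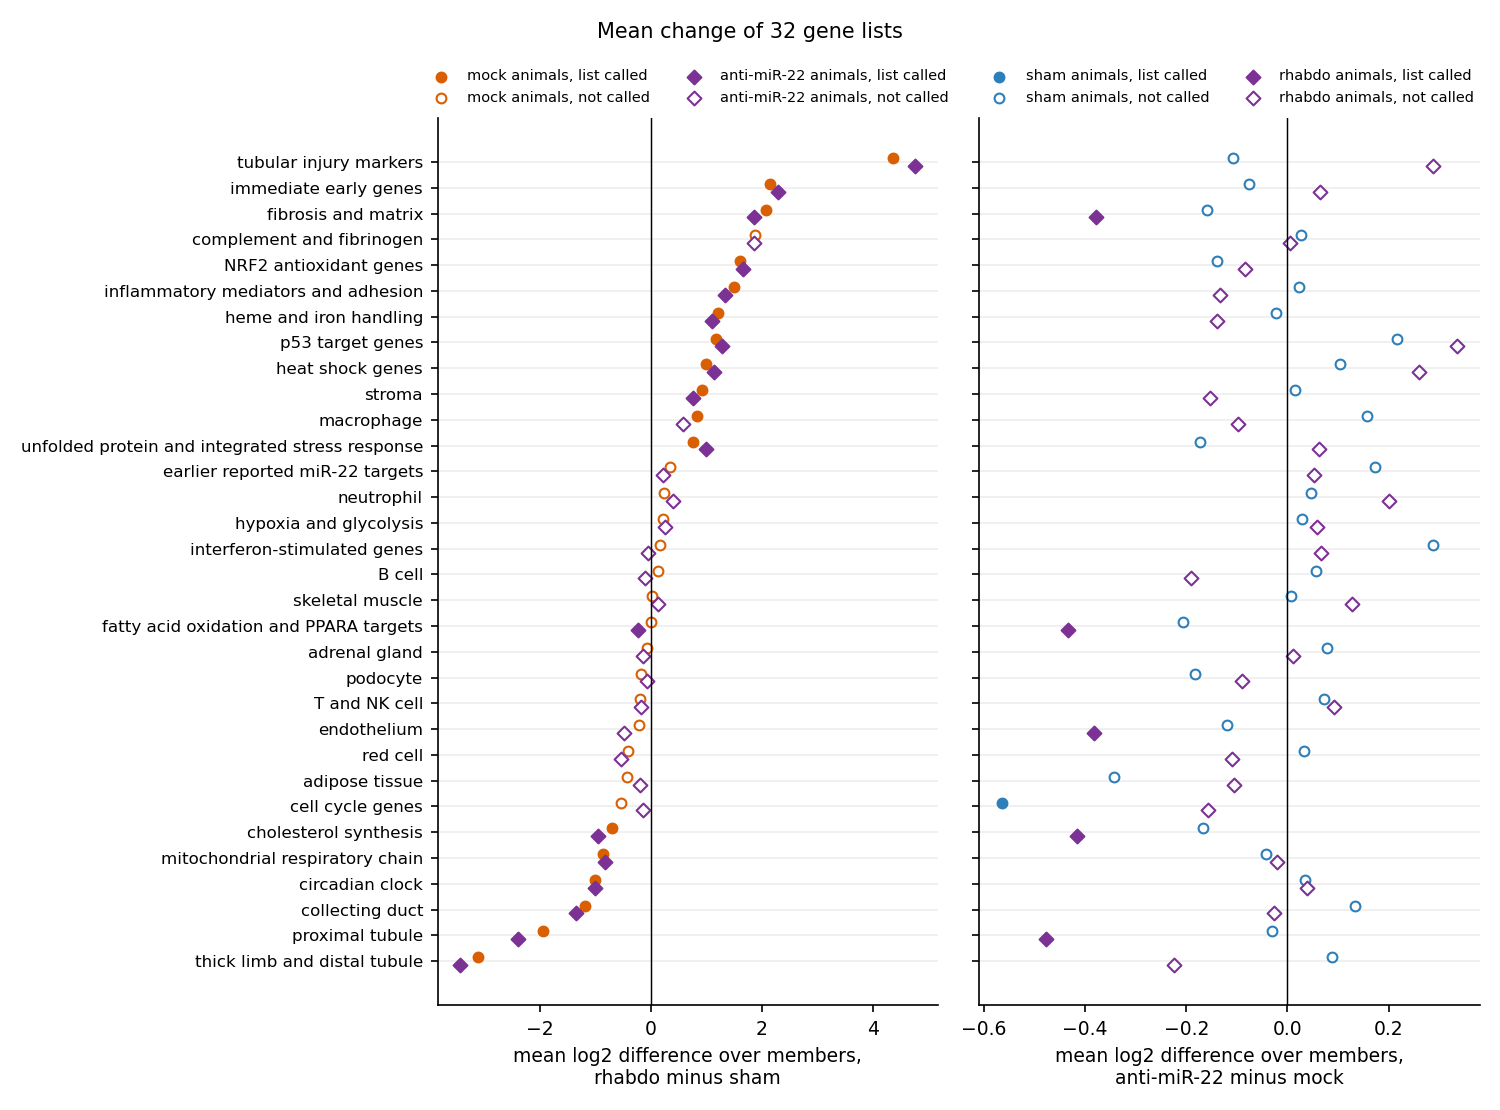
Mean log2 difference of each of the 32 gene lists. The left panel gives rhabdomyolysis minus sham with mock (orange circles) and with anti-miR-22 (purple diamonds), the right panel gives anti-miR-22 minus mock in sham (blue circles) and in rhabdomyolysis (purple diamonds) kidneys, and filled symbols mark lists called by camera at the preset correlation. Tubular injury markers lie at 4.37 and 4.76 in the left panel, and thick limb genes at -3.11 and -3.43.

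Anti-miR-22 was then compared with mock in sham kidneys, where no injury had been induced. The transcription factor gene Foxp1 (probe TC0600003601.mm.2) was 14.9-fold higher with anti-miR-22 (3.90 ± 0.21, n = 5 against 5, adjusted p = 2.8e-13), with a group mean of 11.45 ± 0.15 (SD) against 7.55 ± 0.41. Ppdpf was 10.3-fold higher, the Mediator subunit gene Med15 6.27-fold and the RNA-binding repressor gene Pum2 4.48-fold. Cst3, which encodes cystatin C, was 4.89-fold lower (-2.29 ± 0.16, adjusted p = 3.82e-11), the lipid phosphatase gene Plpp2 4.38-fold lower and the fatty acid elongase gene Elovl1 3.44-fold lower. 1590 probes (7.16%) were called, 854 higher and 736 lower.

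Further genes with higher values were Atxn7l1 (1.98 ± 0.20), Fbxo6 (1.97 ± 0.20), the cytochrome oxidase assembly gene Cox20 (1.97 ± 0.21) and Leng8 (1.97 ± 0.26), and further lower genes were the ribosomal protein gene Rps25 (-1.98 ± 0.16), Card19 (-1.96 ± 0.21), Abracl (-1.93 ± 0.20) and the ubiquitin-like gene Ubl5 (-1.84 ± 0.19). The cell cycle gene Cdca3 was lower as well (-2.03 ± 0.56, adjusted p = 0.0204), but not in 8 alternatives (0.0692 to 0.238), among them the fits without sham mock 2 (adjusted p = 0.0753), sham mock 3 (0.0934) or sham anti-miR-22 array 3 (0.0812). Without sham mock 4 its difference was -2.67 (adjusted p = 0.000484). Among other listed genes, Ccn2 (-1.78 ± 0.23), the cholesterol synthesis gene Msmo1 (-1.47 ± 0.21) and the thioredoxin gene Txn1 (-1.36 ± 0.12) were lower, and the pyruvate kinase gene Pkm was higher (1.54 ± 0.14). The injury genes did not pass, with Havcr1 at -1.72 ± 0.79 (adjusted p = 0.231), Lcn2 at -0.80 ± 0.59 (0.552), Hmox1 at -0.10 ± 0.21 (0.878) and Cdkn1a at 0.68 ± 0.27 (0.139). Without sham mock 1 the differences were -0.27 for Havcr1 (adjusted p = 0.61), 0.27 for Lcn2 (0.546) and 0.11 for Hmox1 (0.855), so that the sign of Lcn2 and Hmox1 turned. Cdkn1a passed in 4 alternatives (adjusted p from 0.000451 to 0.0331), among them the fits without sham mock 1 and without sham mock 3.

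Earlier reported targets of miR-22 moved in both directions in sham kidneys. Of 26 measured, 5 were higher and 3 lower, or 8 and 3 adjusted over the list alone, and the list was not called (mean 0.17, camera adjusted p = 0.0503; adjusted p = 0.967 with an estimated correlation). The exact permutation p of its score was 0.0159 (adjusted 0.0847), and fry gave an adjusted p of 0.0157. The histone deacetylase gene Hdac4 (0.83 ± 0.16) and the stress gene Trp53inp1 (0.95 ± 0.18) were higher, and the fatty acid oxidation regulator Ppara (-1.08 ± 0.20) and the cell cycle kinase gene Cdk6 (-0.93 ± 0.17) were lower. The p53 targets, with Mdm2, which encodes the ubiquitin ligase of p53, 3.08-fold higher, were not called (3 of 14 higher, or 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.34). Their score was higher by 0.216 and that of interferon-stimulated genes by 0.288, each at an exact permutation p of 0.00794, the smallest possible. After adjustment 0 of 32 list scores passed in sham kidneys. With 5 against 5 arrays even a score at the smallest possible p does not pass unless several lists reach it. This 0 therefore does not show that no list shifted. The list called was that of cell cycle genes, which was lower (mean -0.56, adjusted p = 0.00475; adjusted p = 0.98 with an estimated correlation), although 1 of its 20 members passed by either adjustment, the thymidylate synthase gene Tyms (-0.89 ± 0.23). The exact permutation p of the list's score was 0.373 (adjusted 0.597). Without sham mock 3 the list's adjusted p was 0.782 and its mean -0.13, and without sham anti-miR-22 array 3 the adjusted p was 0.096, in a range of 0.096 to 0.98 over the 7 alternatives that ended the call. Tyms had an adjusted p of 0.0611 without sham mock 3, and of up to 0.175 in the 3 alternatives that ended its call.

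**Figure D4:**
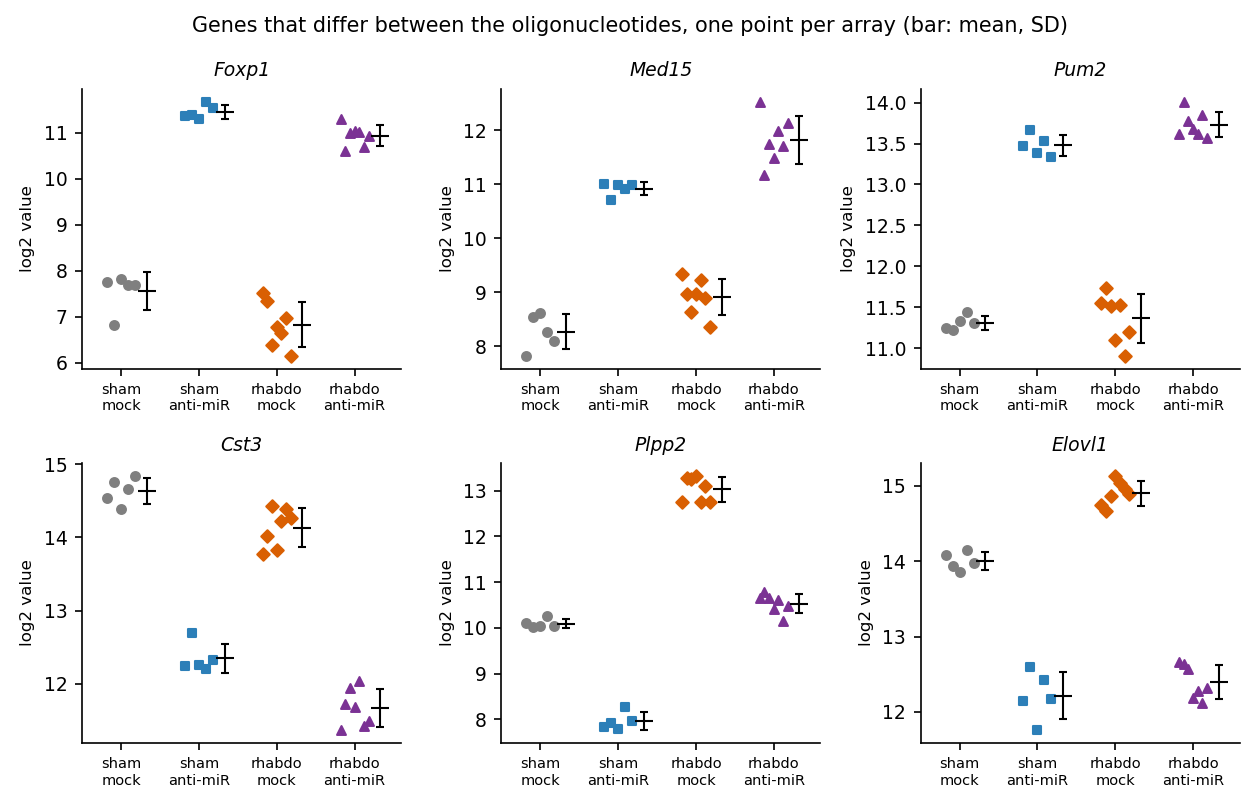
Log2 array values of Foxp1, Med15, Pum2, Cst3, Plpp2 and Elovl1 in the 4 groups, with 1 point per array and the group mean with its SD. The first 3 genes are higher with anti-miR-22 and the other 3 lower, in sham and in rhabdomyolysis kidneys.

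The same comparison in rhabdomyolysis kidneys asked what differs between anti-miR-22 and mock after injury. Foxp1 was 17.3-fold higher with anti-miR-22 (4.11 ± 0.18, n = 7 against 7, adjusted p = 6.53e-16), Leng8 8.58-fold, Ppdpf 8.03-fold and Med15 7.52-fold. Card19 was 5.77-fold lower, Elovl1 5.68-fold, Plpp2 5.65-fold and Cst3 5.53-fold. Havcr1 (0.13 ± 0.67, adjusted p = 0.935), Lcn2 (0.08 ± 0.50, 0.946), Hmox1 (-0.06 ± 0.18, 0.884) and Cdkn1a (0.56 ± 0.23, 0.0835) did not pass, although Cdkn1a passed in 4 alternatives (0.0118 to 0.05), among them the fit without sham mock 4. 4360 probes (19.6%) were called, 2106 higher and 2254 lower.

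The oligonucleotide effects in sham and rhabdomyolysis kidneys, which share 0 arrays, correlated across probes at r = 0.603 (Spearman rho = 0.426). Both comparisons called 1221 probes, 1218 of them with the same sign. 630 were higher in both where independent lists would give 81, and 588 were lower in both where they would give 74.71. Here too the shared estimate of spread per probe can raise the overlap. Of the probes called in sham kidneys, 76.6% were called with the same sign after glycerol. Other high genes were the cyclophilin gene Ppic (2.53 ± 0.16), the nuclear pore gene Nup54 (2.52 ± 0.13), the Mediator gene Med12 (2.40 ± 0.18), Cox20 (2.37 ± 0.17), Pum2 (2.36 ± 0.12) and the RNA-binding gene Ewsr1 (2.30 ± 0.13). Other low genes were Ubl5 (-2.38 ± 0.16), Msmo1 (-2.30 ± 0.18), the peptide transporter gene Slc15a3 (-2.26 ± 0.17) and Scp2, whose product carries sterols (-2.16 ± 0.15).

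**Figure D5:**
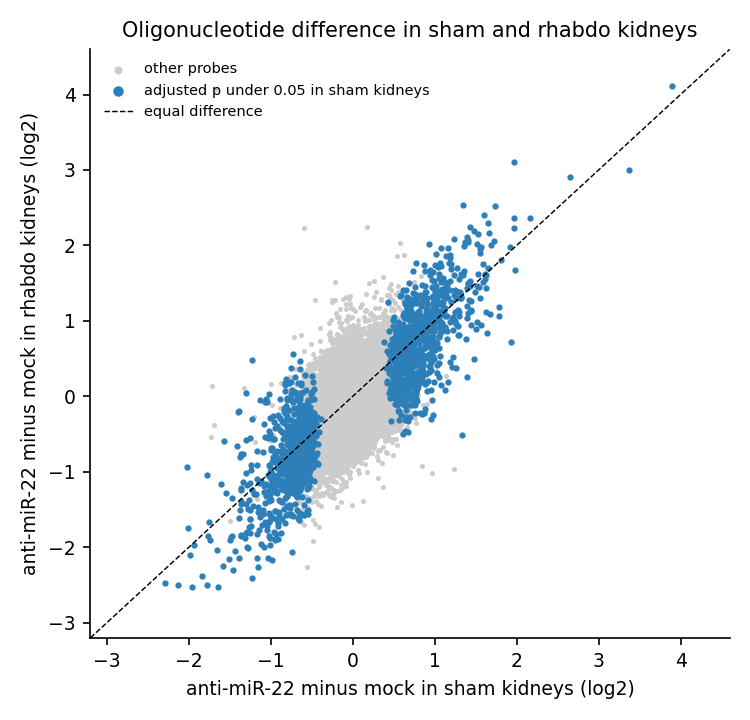
Each point is a probe, with its log2 difference between anti-miR-22 and mock in sham kidneys on the x axis and in rhabdomyolysis kidneys on the y axis. Blue points had an adjusted p below 0.05 in sham kidneys, the dashed line marks equal differences, and r over all probes was 0.603.

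Several lists were lower with anti-miR-22 after glycerol, each at the preset correlation and none with an estimated one. Proximal tubule genes had 11 of 21 lower and 2 higher by either adjustment (mean -0.48, adjusted p = 0.000506; adjusted p = 0.741 with an estimated correlation; exact permutation p of the score 0.00699, adjusted 0.0448). The dicarboxylate transporter gene Slc13a3 (-1.91 ± 0.30) and Slc7a13 (-1.42 ± 0.25) were lower, while Gatm (0.77 ± 0.26, adjusted p = 0.034) and Acsm2 (0.70 ± 0.11) were higher. Gatm had an adjusted p of 0.0565 to 0.105 in 9 alternatives, among them the fits without rhabdomyolysis mock 2, 3, 4 or 7 or rhabdomyolysis anti-miR-22 array 5 or 6. Fatty acid oxidation genes had 9 of 20 lower and 3 higher, or 10 and 4 adjusted over the list alone (mean -0.43, adjusted p = 0.00643; adjusted p = 0.741 with an estimated correlation; exact permutation p 0.0117, adjusted 0.0456). Hadhb, a subunit of the mitochondrial trifunctional protein (-1.91 ± 0.13), and Ppara (-1.67 ± 0.17) were lower, and Plin2 (0.64 ± 0.19) and the coactivator gene Ppargc1a (0.47 ± 0.16, adjusted p = 0.0351) were higher, the last with an adjusted p of 0.051 to 0.0958 in 9 alternatives, 7 of them the omission of 1 array. Cholesterol synthesis had 5 of 14 lower and 0 higher, or 6 lower adjusted over the list alone (adjusted p = 0.0154; adjusted p = 0.741 with an estimated correlation; exact permutation p 0.00524, adjusted 0.042), including Msmo1 and Hmgcs1 (-1.11 ± 0.13). Leaving out dim probes also ended the camera calls of cholesterol synthesis (adjusted p = 0.161) and fatty acid oxidation (0.113). The cholesterol call ended as well without sham mock 1 and 3, rhabdomyolysis mock 6 and rhabdomyolysis anti-miR-22 array 2 (0.0774).

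Matrix genes had 8 of 18 lower and 0 higher, or 9 lower adjusted over the list alone (mean -0.38, adjusted p = 0.00428; adjusted p = 0.687 with an estimated correlation). The fibronectin gene Fn1 (-1.17 ± 0.19) and Ccn2 (-1.04 ± 0.20) were among them. Endothelium markers had 5 of 11 lower and 2 higher, or 7 and 2 adjusted over the list alone (mean -0.38, adjusted p = 0.0417; adjusted p = 0.741 with an estimated correlation). Kdr (-1.62 ± 0.14) and the fenestral diaphragm gene Plvap (-0.91 ± 0.12) were lower, while Robo4 (0.57 ± 0.12) and Eng (0.46 ± 0.15, adjusted p = 0.0239) were higher. The exact permutation p of the score was 0.000583 (adjusted 0.00932) for matrix and for endothelium, the smallest that 7 arrays against 7 can give. Without rhabdomyolysis mock 1 (adjusted p = 0.125), rhabdomyolysis mock 6 (0.0574) or rhabdomyolysis anti-miR-22 array 2 (0.0612) the endothelium list was not called, in a range of 0.0574 to 0.741 over 7 alternatives, and Eng had an adjusted p of 0.0533 to 0.0632 without rhabdomyolysis mock 6 or 7 or rhabdomyolysis anti-miR-22 array 1 or 4.

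Other lists were not called by camera in injured kidneys. Injury markers had 6 of 23 higher and 2 lower, or 7 and 3 adjusted over the list alone (adjusted p = 0.274; exact permutation p of the score 0.0111, adjusted 0.0456). The cornified envelope gene Sprr2f (2.25 ± 0.32) and the tight junction gene Cldn4 (1.68 ± 0.21) were higher, and Krt20 was lower (-1.22 ± 0.39, adjusted p = 0.023), with an adjusted p of 0.0501 to 0.069 in 6 alternatives, among them the fits without rhabdomyolysis mock 4 or 7 or rhabdomyolysis anti-miR-22 array 5 or 6. The p53 targets Mdm2 (1.44 ± 0.19) and Plk2 (1.16 ± 0.17) were higher, with 3 of 14 members higher and 1 lower, or 6 and 1 adjusted over the list alone (mean 0.34, adjusted p = 0.126; exact permutation p of the score 0.0117, adjusted 0.0456). Earlier reported miR-22 targets had 8 of 26 higher and 4 lower, or 12 and 5 adjusted over the list alone (adjusted p = 0.716), with Hdac4 (0.92 ± 0.13) and the receptor gene Erbb3 (0.74 ± 0.16) higher and Ppara and Cdk6 (-1.16 ± 0.15) lower. Inflammatory mediators had 4 of 26 lower by either adjustment and 0 higher (adjusted p = 0.668; exact permutation p of the score 0.0128, adjusted 0.0456), the chemokine gene Cxcl10 among them (-1.30 ± 0.26), and their mean of -0.13 differed in sign from their median of 0.02. In complement and fibrinogen, 2 of 13 were higher and 2 lower by either adjustment (adjusted p = 0.819), with C4b at 0.91 ± 0.15 and Fgb at -1.44 ± 0.34. B cell markers had 1 of 7 lower, or 2 adjusted over the list alone (mean -0.19, adjusted p = 0.58), and an exact permutation p of the score of 0.00524 (adjusted 0.042).

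Whether glycerol acted differently under the 2 oligonucleotides was tested as the difference between their effects. Zbtb16, a zinc finger transcription factor gene, had the highest value (2.82 ± 0.41, adjusted p = 0.00135), with a mean of 9.62 in rhabdomyolysis anti-miR-22 kidneys against 7.4 with mock, and 7.56 against 8.16 in sham kidneys. Ttpa, which encodes the vitamin E transfer protein (1.74 ± 0.34), the kinase gene Pim3 (1.5 ± 0.30), Golm1 (1.46 ± 0.26) and Rgcc (1.44 ± 0.27) followed. Slc15a3 (-1.70 ± 0.26), the phospholipase gene Plch1 (-1.56 ± 0.36), the dynactin gene Dctn4 (-1.39 ± 0.19), the dopa decarboxylase gene Ddc (-1.32 ± 0.27) and the viral RNA sensor gene Ifih1 (-1.23 ± 0.25) had the lowest values. 85 probes (0.383%) were called, 46 higher and 39 lower, and 2746 had an unadjusted p below 0.05.

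The interaction was called for few members of any list. Injury markers as a list were higher (mean 0.40, adjusted p = 0.0321; adjusted p = 0.534 with an estimated correlation), with 1 of 23 called, or 2 adjusted over the list alone, the AP-1 gene Fosl1 (1.34 ± 0.29). Proximal tubule genes were lower (mean -0.45, adjusted p = 5.05e-05; adjusted p = 0.517 with an estimated correlation), with 0 of 21 called, or 6 lower adjusted over the list alone. Thick limb (mean -0.31, 0.027, with 0 called by either adjustment) and endothelium (mean -0.26, 0.027, with 1 lower, or 3 adjusted over the list alone, the called gene being Kdr at -0.95 ± 0.22) were lower too, both at an adjusted p = 0.517 with an estimated correlation. Fatty acid oxidation was lower (mean -0.23, adjusted p = 0.0321; adjusted p = 0.534 with an estimated correlation), with Hadhb called (-0.96 ± 0.20) and 5 lower adjusted over the list alone. Permutation tests of the score differences gave no adjusted p below the threshold, with 0.0181 (adjusted 0.202) for proximal tubule and 0.0119 (adjusted 0.202) for thick limb. Without sham mock 1, whose injury markers were high, the injury list had a mean of 0.13 with an adjusted p of 0.542 and fatty acid oxidation one of 0.0529, and without rhabdomyolysis mock 6 all but the proximal tubule list lost their calls (0.0507 to 0.0776). Without sham anti-miR-22 array 3 the fatty acid oxidation mean was -0.13 (adjusted p = 0.131). The count of 85 probes fell to 28 without rhabdomyolysis anti-miR-22 array 4 and was 138 without rhabdomyolysis mock 3.

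The oligonucleotide effects in sham and rhabdomyolysis kidneys were also averaged, and a call of this mean does not require a change in both. Foxp1 was 16-fold higher (4.00 ± 0.14, adjusted p = 1.07e-18), followed by Ppdpf (3.19 ± 0.14), Med15 (2.78 ± 0.13), Leng8 (2.53 ± 0.17) and Pum2 (2.26 ± 0.09). Cst3 (-2.38 ± 0.10), Plpp2 (-2.31 ± 0.10), Card19 (-2.24 ± 0.14), Elovl1 (-2.14 ± 0.10) and Ubl5 (-2.11 ± 0.13) were lowest. Mdm2 (1.53 ± 0.15) and Cdkn1a (0.62 ± 0.17, adjusted p = 0.00976) were higher. 4322 probes (19.5%) were called, 2052 higher and 2270 lower.

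Of the earlier reported miR-22 targets, 12 of 26 were higher on average and 3 lower, or 12 and 4 adjusted over the list alone, without a call by camera (mean 0.11, adjusted p = 0.155). Hdac4 (0.87 ± 0.10) and Erbb3 (0.68 ± 0.13) were higher and Ppara (-1.37 ± 0.13) lower. Camera called lower means for proximal tubule (8 of 21 lower and 2 higher, or 10 and 2 adjusted over the list alone), matrix (5 of 18 lower, or 8 adjusted over the list alone) and fatty acid oxidation (6 of 20 lower and 2 higher by either adjustment), each at an adjusted p of 0.0292, and for cholesterol synthesis (6 of 14 lower, or 6 lower and 2 higher adjusted over the list alone, 0.0396). With an estimated correlation these were not called (adjusted p = 0.898 for proximal tubule and adjusted p = 0.888 for the others), and without rhabdomyolysis mock 6 none of the 4 was called at the preset correlation.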

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

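The tests of RNA mixing, of a sample swap, and of the proximal tubule, endothelium, matrix and cell number explanations were chosen only after the result was seen. The mixing test was divided into 2 parts after its first form gave no verdict, and the Havcr1 part was then widened from the fibrinogen genes alone to all genes that rose at least 16-fold. The correlation over all probes and the splits of the samples were planned.

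Within each group, an array was singled out when its gap to the nearest other array, as a share of the group's range, passed Dixon's critical value for the number of arrays in the group. That held for 17 of 320 groups of gene values and 11 of 128 groups of list scores, where chance alone picks about 1 in 20 groups.

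In sham mock 1, Havcr1 (share 0.902), Lcn2 (0.805), Plin2 (0.785), Tnfrsf12a (0.773) and the tubular injury score (0.765) were high, with Plin2 at 11.67 against 9.99 to 10.35 and Tnfrsf12a at 9.88 against 8.38 to 8.72. A swap with a rhabdomyolysis sample is argued against, since 0 rhabdomyolysis arrays correlated best with a sham mean and sham mock 1 correlated at 0.995 with the other sham mock arrays and at 0.9697 with rhabdomyolysis mock. RNA of an injured kidney mixed into this sample cannot be told apart from injury of this kidney. The shares given next take 2 raised to the log2 value as proportional to RNA amount, which was not checked, so the scale alone could shift them. At the 5.75% of injured kidney RNA that Havcr1 implies, the 53 other genes that rose at least 16-fold had a median -0.8 from the prediction (quartiles -1.24 and -0.407), short of the bound set, and 40 of them were higher than in each other sham mock array. The shares that these genes imply had a median of 2.06% (quartiles 0.659% and 3.37%), which leaves Havcr1 1.466 above its predicted level at the median and 0.766 at the upper quartile, with 0.508% for Fga, 2.83% for Hmox1, 3.19% for Lcn2 and 4.92% for Mt2; the design names no biological difference for this animal, so none was tested.

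Sham mock 3 stood apart high for Aqp3 (0.772), Cp (0.733) and the adrenal gland score (0.757), and low for Ccn2 (0.773), the proximal tubule score (0.731) and the macrophage score (0.865). Sham mock 4 was high for Atp5b (0.835) and low for Hlf (0.764). Foxp1 was low in sham mock 2 (0.865; 6.82 against 7.68 to 7.81), and the immediate early score was high in sham mock 5 (0.929). In sham anti-miR-22 array 2, Cst3 was high (0.76) and the inflammatory score low (0.812). In sham anti-miR-22 array 3, the fatty acid oxidation score was high (0.73) and the circadian clock score low (0.834).

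Among rhabdomyolysis anti-miR-22 arrays, Ppic was low (0.701) and the endothelium score high (0.715) in array 1, Ppdpf low in array 2 (0.709), Slc12a1 low in array 4 (0.664) and Sox9 low in array 5 (0.762; 10.21 against 12.17 to 12.78). Among rhabdomyolysis mock arrays, Hmgcs1 was low in array 2 (0.639), Cldn4 low in array 6 (0.58), and in array 4 the miR-22 target score was low (0.574) and the stroma score high (0.624).

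The glycerol response differed between oligonucleotides, by the interaction test, for Zbtb16 (2.821), Ttpa (1.737), Pim3 (1.495), Golm1 (1.457), Rgcc (1.437), Fosl1 (1.344), Ppic (1.183), Slc15a3 (-1.695), Plch1 (-1.562), Dctn4 (-1.392), Ddc (-1.321), Ifih1 (-1.233), Hadhb (-0.956) and Kdr (-0.955). By camera it differed for the injury marker (0.395), fatty acid oxidation (-0.227), proximal tubule (-0.447), thick limb (-0.313) and endothelium (-0.263) lists, none of which was called with an estimated correlation (adjusted p from 0.517 to 0.534) or by fry. Of 100 splits of the samples, 1, the real one, called as many as its 85 probes, and the highest other called 2. These splits cannot exclude chance for the count. They redrew the oligonucleotide labels, which moves the oligonucleotide effect shared by sham and rhabdomyolysis kidneys into the spread and leaves few calls. Which genes were called depends on single arrays. Kdr lost its call in 20 alternatives (adjusted p from 0.0503 to 0.0878), Plch1 in 17 (0.0512 to 0.0877), Fosl1 in 11 (0.0502 to 0.105), Hadhb in 8 (0.0502 to 0.114), Ifih1 in 4 (0.0507 to 0.0793), Ttpa in 2 (0.077 to 0.101) and Ddc in 2 (0.0504 to 0.0655), and 18, 16, 8, 6, 2, 0 and 1 of these were the omission of 1 array.

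The proximal tubule, matrix and endothelium lists, lower with anti-miR-22 in rhabdomyolysis kidneys at the preset correlation but not with an estimated one (adjusted p = 0.741, 0.687 and 0.741; the endothelium call ended in 7 alternatives, at 0.0574 to 0.741), were weighed against deeper injury and a loss of cells. Deeper injury may account for the proximal tubule list, whose score moved by -1.945 with glycerol in mock animals and by -0.477 with anti-miR-22. The endothelium score was lower in both comparisons too, but by -0.209 with glycerol and -0.383 with anti-miR-22. Its direction goes with deeper injury, while its size does not follow from it. The thick limb score, at -3.114 with glycerol, lay at -0.225 with anti-miR-22 (exact permutation p = 0.053). Deeper injury is argued against for the matrix list, which glycerol raised by 2.08 and which lay at -0.378 with anti-miR-22. These comparisons share the rhabdomyolysis mock arrays. Of 9 lists whose scores differed in both comparisons by unadjusted exact permutation p, 6 moved the same way, among them injury markers (0.288 with anti-miR-22, camera adjusted p = 0.274), and 3 moved opposite ways, the matrix, inflammatory mediator (-0.134) and heme and iron (-0.139) lists. Over all probes deeper injury stays open, since the correlation of the effects over 35 splits without shared arrays averaged 0.051 and ran from -0.011 to 0.113, and Havcr1 (0.13), Lcn2 (0.08) and Hmox1 (-0.06) did not pass the test between oligonucleotides. On the first principal component rhabdomyolysis anti-miR-22 arrays (48.62 to 63.18) lay further from sham than rhabdomyolysis mock arrays (39.32 to 52.07), with some overlap. Whether depth of injury sets this offset was not tested. Fewer proximal tubule cells alone would leave the other kidney cell types higher. The endothelium score, at -0.383 (exact permutation p = 0.000583), argues against that, although members of its list went both ways. The collecting duct (-0.027), podocyte (-0.089) and stroma (-0.153) scores were not higher either, but none of these had an exact permutation p below 0.05.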

How the results depend on the processing

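The fits without sham mock 1 and 3, and without these, rhabdomyolysis mock 6 and rhabdomyolysis anti-miR-22 array 2, were chosen after seeing the data. No called result changed direction. Of 178 named gene results, 159 kept direction and side of the threshold in every alternative, as did 25 of 49 list calls. Across settings, gene results became weaker 94 times when 1 array was left out and 33 times otherwise, and stronger 3 and 5 times. List results became weaker 34 and 67 times. For anti-miR-22 in sham kidneys, Lcn2 and Hmox1, called in none of the fits, turned from lower to higher without sham mock 1 (0.272 and 0.111) and both without sham mock 1 and 3 and without the 4 arrays (0.21 and 0.195 in each). Over the omission of 1 array they ran from -1.216 to 0.272 and from -0.242 to 0.111. The cause was not tested, except that fewer arrays or probes were used where so named. No measure of signal over background was used, and dim probes limit small differences.

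The interaction count of 85 was 173 with trend and robust moderation, 141 with array weights and 136 after quantile normalization, each holding all 85. It was 267 without dim probes (82 shared), 34 without sham mock 1 and 3 (30 shared) and 53 without the 4 arrays (36 shared). Leaving out 1 array gave 28 to 138: sham mock 2 gave 51, 3 gave 34, 4 gave 56 and 5 gave 54, sham anti-miR-22 array 1 gave 30, 2 gave 45, 4 gave 40 and 5 gave 55, rhabdomyolysis mock 3 gave 138 and 5 gave 39, and rhabdomyolysis anti-miR-22 array 4 gave 28 and 6 gave 49. A 2-fold minimum left 2822 probes for glycerol with mock, 3248 with anti-miR-22, 316 for anti-miR-22 in sham, 729 in rhabdomyolysis, 49 for the interaction and 421 for the mean effect.

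Other counts stayed within 1.5 times. Leaving out 1 array gave 7121 to 7734 for glycerol with mock, 7794 to 8464 with anti-miR-22, 1351 to 1702 for anti-miR-22 in sham, 4002 to 4413 in rhabdomyolysis and 4048 to 4396 for the mean. Without sham mock 1 and 3 these counts were 6892, 8293, 1100, 4379 and 3798, and without the 4 arrays 7001, 8333, 1295, 4183 and 3940.

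Called lists for anti-miR-22 in sham (1) were 3 after quantile normalization, 2 with the replicate block, and 0 without dim probes, with an estimated correlation, without sham mock 1 and 3, and without the 4 arrays. Leaving out 1 array gave 0 to 3. The count was 0 without sham anti-miR-22 array 3, 2 without sham mock 1, 2 or 4, sham anti-miR-22 array 1, rhabdomyolysis mock 6 or rhabdomyolysis anti-miR-22 array 2, and 3 without sham anti-miR-22 array 4, rhabdomyolysis mock 1, 3 or 4 or rhabdomyolysis anti-miR-22 array 5. In rhabdomyolysis (5) they were 2 without dim probes, 0 with an estimated correlation and 3 without the 4 arrays. For the interaction (5) they were 1 without dim probes, 0 with an estimated correlation, 0 by fry, 2 without sham mock 1 and 3 and 1 without the 4 arrays. Leaving out 1 array gave 1 to 9, with 9 without rhabdomyolysis mock 1, 8 without sham mock 4 or rhabdomyolysis anti-miR-22 array 5 or 6, 3 without rhabdomyolysis mock 5, and 1 without rhabdomyolysis mock 6 or rhabdomyolysis anti-miR-22 array 3. For the mean effect (4) they were 0 after quantile normalization, without dim probes, with an estimated correlation and without the 4 arrays, and 8 by fry. Leaving out 1 array gave 0 (rhabdomyolysis mock 6) to 6 (rhabdomyolysis anti-miR-22 array 5).

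Whether replicate numbers pair the samples stays open. Over 32 same-number pairs the deviations correlated at -0.108 to 0.102, with a median of 0.0107 and 1 above 0.1. The highest values, 0.102, 0.0912 and 0.0866, were those of rhabdomyolysis mock with rhabdomyolysis anti-miR-22 arrays 1, 2 and 3, while arrays 7 of these groups gave -0.0186. In 16 of 64 comparisons an array correlated best with its own number, and the share expected by chance was not computed. With the replicate block the counts were 7366, 8060, 1562 and 4451 for the comparisons in the order above, 89 for the interaction and 4382 for the mean. The block ended the calls of Kdr in the interaction (adjusted p = 0.0506) and of stroma for glycerol with anti-miR-22 (0.0531) and no other call of a named gene or list. The planned test of miR-22 seed sites was not run.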

Other observations

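The comparison of miR-22 targets with matched random lists was chosen only after the result was seen, while the permutation and camera tests of that list were planned. The glutamine tract list was written, and its test planned, before its values were looked at, but the idea came from seeing Foxp1, Med15 and Med12 among the genes that differed most, and these were left out of the list.

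Genes listed for glutamine tracts in their proteins, which CAG and CAA codons encode, were higher with anti-miR-22 than with mock. The tracts were not checked in mouse sequences, so some members, Atxn2 included, may lack one in the mouse. Of 33 measured, 19 were higher on average over sham and rhabdomyolysis kidneys and 1 lower, Irf2bpl (-0.40 ± 0.13, adjusted p = 0.0264). Within sham kidneys 15 were higher and 0 lower, and within rhabdomyolysis kidneys 17 were higher and 0 lower. Atxn2, a gene of RNA metabolism, was higher by 1.53 ± 0.13, the zinc finger gene Zfp384 by 1.36 ± 0.10, the muscle and neuron transcription factor gene Mef2a by 1.32 ± 0.08, the chromatin remodelling gene Arid1b by 1.18 ± 0.09, Foxp2 by 1.12 ± 0.14, Bmp2k by 1.09 ± 0.12 and the huntingtin gene Htt by 0.88 ± 0.12. Mediator subunits listed as without such a tract, which was not checked in sequences, went both ways on average, with 9 of 25 higher and 5 lower. Within sham kidneys 3 were higher and 0 lower, and within rhabdomyolysis kidneys 8 were higher and 4 lower. On average Cdk8 was higher by 1.25 ± 0.15 and Med28 by 1.20 ± 0.10, while Med23 lay at -0.65 ± 0.10.

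A candidate explanation for the higher values of these genes in sham and in rhabdomyolysis kidneys is that the mock oligonucleotide lowers transcripts with CAG repeats, since its longest stretch complementary to such a repeat is 6 bases, against 3 for anti-miR-22. The glutamine tract list had a median of 0.512, at percentile 100 of 10000 random lists matched on level (highest 0.233), and its score was higher by 0.506 in sham (exact permutation p = 0.00794, the smallest possible) and by 0.534 in rhabdomyolysis kidneys (exact permutation p = 0.000583, the smallest possible). The Mediator list lay at percentile 70.7, although its score was higher too, by 0.108 in sham (exact permutation p = 0.0397) and by 0.273 in rhabdomyolysis kidneys (exact permutation p = 0.000583). Anti-miR-22 raising its earlier reported targets stays open beside this, with the median of 0.19 at percentile 99.6, an exact permutation p of 0.0159 in sham and 0.253 in rhabdomyolysis kidneys, and a p of 0.104 by camera with an estimated correlation. No group without an oligonucleotide was analysed here, so a fall with mock cannot be separated from a rise with anti-miR-22, and neither array batch nor repeats in the transcripts themselves were tested.

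Of 100 splits of the samples 1, the real one, called as many probes in each comparison other than the interaction. Random labelling of these arrays therefore seldom gives such counts. The splits treat each array as independent, so they cannot exclude a batch or a shared origin that follows the groups. The real count and the highest other were 7641 and 4667 for glycerol with mock, 8303 and 5122 for glycerol with anti-miR-22, 1590 and 7 for anti-miR-22 in sham kidneys, 4360 and 1879 for anti-miR-22 in rhabdomyolysis kidneys, and 4322 and 4 for the mean oligonucleotide effect.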
